A study of Arabidopsis thaliana with 12 samples.

How the data were processed

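The series holds 12 poly-A RNA libraries of whole Arabidopsis seedlings in the Col-0 background, 3 each of WT, smax1-2, the single mutant smxl5-1 and the double mutant smxl4-1 smxl5-1. Per the labels the seedlings were 7 days old, grown in 12 h light and 12 h dark at 21 °C, and each replicate pooled 15 seedlings. Only the deposited processed tables were used, 1 per library, and no reads were processed again. Per the submitters' processing notes the reads were aligned with TopHat2 2.0.14 to TAIR10. The column names of the tables are those that Cuffcompare writes for transcript pieces (transfrags) that Cufflinks assembled, which is inferred from the file headers alone. The assembler's version, its settings, the strand protocol and the annotation release are not given in the sources used here. Per the series design text the authors called differential expression with DESeq2, and a table of that result is not analysed here.

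Each row of a deposited table is 1 transfrag assembled in 1 library. Its abundance is in FPKM per the file headers, fragments per kilobase of the transfrag scaled to the size of the library, with lower and upper bounds. The deposited coverage is a signal, the mean read depth of the transfrag, and within each file it was a constant multiple of the FPKM. The deposited relative abundance is a percent of the most abundant transfrag of its locus. The deposited lengths of the transfrag and of the matched reference transcript are in bases. Gene symbols of the tables were not used to join libraries, because 10 had been turned into dates, and genes were joined by their locus identifier. Locations and names come from the TAIR10.1 annotation, which holds 20728 of the 20869 genes with a value.

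A gene's value was summed over its transfrags that match, lie within, share a junction with or overlap a reference transcript (class codes =, c, j, e and o, 345442 of 353616 transfrags). Each FPKM was multiplied by the ratio of the effective length of the transfrag, not counted beyond the reference length, to that of the reference transcript. This restores fragments per reference transcript, because a short piece of a gene has a high FPKM. The effective length assumed a fragment length of 200 ± 80 bases, the default of the tool whose header the tables carry and not a stated value. Of 4 definitions compared by the median SD within groups before any comparison was looked at, this one gave 0.181, no limit on transfrag length 0.177, plain length 0.242 and a plain sum of FPKM 0.659. The definition used is not the one with the smallest spread. It was used because a transfrag longer than its reference runs into other sequence. A gene with no such transfrag in a library was set to 0. Intronic, antisense, run-on and intergenic transfrags (2.31% of the total with the other unused classes) were left out of the gene values.

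The plan named counts first and limma on log values if the files held normalized values, and the second applied. The genes with at least 1 FPKM in at least 3 libraries, 18879 in all, were tested with limma 3.58.1 (limma-trend) in R 4.3.3 on log2(FPKM + 1), in 1 fit of 12 libraries and 4 groups. The 5 comparisons were each mutant against WT and the double mutant against smxl5-1 and against smax1-2. The last 2 are the tests of the differences between mutants. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The groups, tests, threshold, gene lists and rule for naming genes were fixed before the data were examined. The tables were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

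The 25 gene lists cover the SMXL family, karrikin and strigolactone, phloem, xylem and cambium, anthocyanin and flavonoid, starch synthesis, starch breakdown, sugar starvation, sucrose metabolism and sugar transport, photosynthesis, phosphate starvation, auxin, cytokinin, light and hypocotyl growth, salicylic acid and defence, jasmonate, abscisic acid and dehydration, root hair, RNA silencing, cell cycle, seed storage, circadian clock, heat shock, nitrate, and iron deficiency. They were written from general knowledge of the plant and hold 414 genes, of which 387 had a value. The 24 lists with at least 3 tested genes were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry.

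The text names the mutated genes in every library. It then names, for each comparison and direction, the 6 called genes with the largest absolute log2 fold change among those with a mean of at least 5 FPKM in the higher group and libraries that do not overlap, and up to 4 genes of each list with the smallest p. Members of a count of 5 or fewer and other genes outside this rule are said to be chosen after their values were seen.

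The tables give no counts. Estimated from FPKM and effective length, the libraries held 20467912 to 23928145 fragments, but only 39.0% to 41.7% of the estimates under 200 fragments lay within 0.05 of a whole number, so these are estimates and not recovered counts, and no counting interval is given. The libraries listed 27825 to 31919 transfrags and 18628 to 19022 genes. The share of exact-match transfrags ran from 31.8% to 47.2%, the share of organelle genes from 0.108% to 0.254% and that of the 10 most abundant genes from 9.75% to 11.9%. The first principal component held 14.5% of the variance and the second 13.4%. On the second, smxl5-1 replicate 2 (50.7) and double-mutant replicate 1 (51.1) stood apart from the other 10 libraries (-29.5 to 7.96), and these 2 libraries also had the highest shares of exact-match transfrags (47.2% and 45.6%). Their genotypes differ and the labels give no batch, so both were left out together as 1 of the alternatives.

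The fit was tested on simulated data with the real libraries' spread. It called 70% to 82% of genes with a simulated log2 change of 1, 34% to 46% at 0.5 and 88% to 94% at 2, over the 5 comparisons, with 1.91% to 6.08% false calls. Overlaps and correlations between comparisons that share WT were set beside 100 simulated draws of groups without a change against a shared WT group.

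The alternatives fixed beforehand were quantile normalization, no filter, a stricter filter of 5 FPKM, a pseudocount of 0.1, only the 2 groups compared, adjusted p under 0.01, an absolute log2 fold change of at least 1, a replicate block, the estimated correlation, fry and leaving out each library. Those added after the data were seen were a block by file-name number, median-of-ratios scaling, classes =, c and j alone, the 3 other gene-value definitions, genes listed in all 12 libraries, the exact-match share as covariate, a robust fit, leaving out both libraries with the most exact-match transfrags, and voom on estimated fragments.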

Results

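The SMXL proteins are nuclear regulators related to a heat-shock chaperone, and SMAX1 is the member that karrikin signalling removes in Arabidopsis seedlings. The comparisons ask which genes differ in seedlings that carry smxl4-1 and smxl5-1, and how far these are the genes that differ in smax1-2. Means are FPKM per gene with the SD over n = 3 separate biological replicates, each of 15 seedlings per the labels. Adjusted p values come from limma with Benjamini-Hochberg adjustment over 18879 genes. A gene is given as 0 where no assembled piece of it is listed, since the deposited tables list assembled transcripts only, so a 0 is not a measured absence.

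The transcripts of the mutated genes were looked at first, and none was lower than WT at the threshold in the libraries labelled with its mutation. SMXL5 (AT5G57130, TAIR10.1 chromosome 5, 23144947 to 23149615, plus strand, 4 exons) stood at 3.05, 4.26 and 4.72 FPKM in WT and at 38.8, 39.0 and 38.2 FPKM in the libraries labelled smxl5-1, a log2 fold change of 3.001 (adjusted p = 8.52e-06). In the libraries labelled smxl4-1 smxl5-1, the double mutant, it stood at 7.08, 7.09 and 10.3 FPKM, which was 0.87 higher than WT on the log2 scale (adjusted p = 0.0154, and 0.0507 without WT replicate 1). It stood at 4.89, 5.04 and 5.06 FPKM in smax1-2. With a plain sum of the FPKM of all pieces of the gene, the log2 fold changes of SMXL5 were 3.66 in smxl5-1 and 2.81 in the double mutant, each with a standard error of 0.756 against 0.15 with the gene value used, and neither was called (adjusted p = 0.219 and 0.311). All 6 libraries labelled with smxl5-1 listed a piece of SMXL5 of 129 to 185 nucleotides, and 5 of these 6 listed a piece with a junction that the reference lacks. In the other 6 libraries no piece had such a junction, and the shortest piece ran from 255 to 3162 nucleotides.

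**Figure D1:**
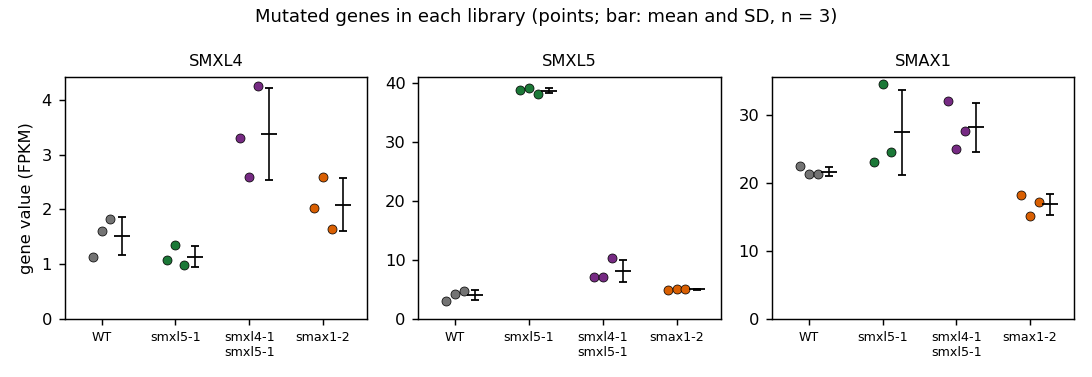
FPKM of SMXL4, SMXL5 and SMAX1 in each library of the 4 genotypes, with points for libraries and bars for the mean and SD of n = 3. SMXL5 lies near 39.0 FPKM in the 3 libraries labelled smxl5-1 and at no more than 10.3 FPKM in the other 9.

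SMXL4 (AT4G29920, chromosome 4, 14632413 to 14636101, minus strand, 3 exons) stood at 1.13, 1.60 and 1.82 FPKM in WT, at 1.08, 1.35 and 0.974 FPKM in smxl5-1, and at 2.02, 2.59 and 1.65 FPKM in smax1-2. In the double mutant it stood at 3.31, 2.58 and 4.25 FPKM, a difference from WT of 0.79 on the log2 scale that did not pass (adjusted p = 0.066). Against smxl5-1 it was higher in the double mutant by 1.02 on the log2 scale (adjusted p = 0.0146, but 0.0606 without double-mutant replicate 3), and stood at -0.28 with the plain sum of FPKM. SMXL5 was lower there by a log2 fold change of -2.14 (adjusted p = 0.000137, and 0.777 with the plain sum of FPKM). SMAX1 (AT5G57710, chromosome 5, 23384255 to 23388465, plus strand, 4 exons) stood at 22.5, 21.3 and 21.3 FPKM in WT, 23.1, 34.6 and 24.7 FPKM in smxl5-1 and 32.1, 24.95 and 27.6 FPKM in the double mutant. In the libraries labelled smax1-2 it stood at 18.2, 15.1 and 17.3 FPKM, with a log2 fold change of -0.35 that did not pass (adjusted p = 0.671). Transcript levels therefore do not identify the mutants, and every direction given here is between libraries as they are labelled.

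In the double mutant the genes that make anthocyanin rose together, from the MYB activator PAP1 to DFR and LDOX, the enzymes that turn dihydroflavonols into anthocyanidins. MYBL2, a repressor of the same pathway, fell. Single genes of starch synthesis (3 of 18) and starch breakdown (4 of 19) rose, and the sugar-starvation genes SEN1 and AKINBETA1 fell. Single genes of dehydration (5 of 18), jasmonate (5 of 16) and iron deficiency (2 of 14) rose as well. None of these 5 lists was called with an estimated correlation between genes (adjusted p = 0.192 to 0.328). With fry, which compares no list with other genes, all 5 were called (0.00618 to 0.0296). SWEET12, which exports sucrose toward the phloem, rose too. Against WT, 466 of the 18879 genes were called, 273 higher and 193 lower, while 2691 had an unadjusted p under 0.05. In each of the 466 all 3 libraries of one group lay above all 3 of the other, which was so for 21.0% of the tested genes, where chance gives 10%. The absolute log2 fold change was at least 1 in 191 of them, and 40 were unlisted in every library of one group. The share of higher calls was 58.6%, but 51.2% of 461 calls with quantile normalization and 47.8% of 475 with median-of-ratios scaling. The count was 203, 223 or 245 without WT replicate 1, 2 or 3, and 267 or 270 without double-mutant replicate 2 or 3.

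Of 17 tested anthocyanin and flavonoid genes, 12 were higher and 1 was lower in the double mutant than in WT (14 and 1 adjusted over the list alone). Their median log2 fold change was 1.59, and this list alone of the 24 tested was called both with the preset correlation (adjusted p = 3.02e-21) and with an estimated correlation (adjusted p = 0.00475). DFR rose from 1.55 ± 1.17 to 91.6 ± 13.8 FPKM (log2 fold change 5.26, adjusted p = 0.000187), and LDOX from 3.14 ± 0.872 to 73.7 ± 14.1 FPKM (adjusted p = 6.69e-05). GSTF12, which is needed to bring anthocyanin into the vacuole, rose from 2.64 ± 0.835 to 51.9 ± 3.70 FPKM (adjusted p = 5.79e-05). PAP1 (AT1G56650) was unlisted in the 3 WT libraries and stood at 13.0, 17.3 and 12.6 FPKM in the double mutant (adjusted p = 7.97e-05). UGT79B1, which adds xylose to anthocyanins, was unlisted in WT and stood at 23.9, 19.95 and 18.5 FPKM (adjusted p = 0.000781). The glucosyltransferases UGT75C1 and UGT78D2 and the malonyltransferase 5MAT rose by log2 fold changes of 2.08, 1.19 and 3.59, but UGT75C1 stood at -1.01 with the plain sum of FPKM. Earlier steps rose as well, with CHS, chalcone synthase, going from 94.7 to 238 FPKM (log2 fold change 1.33, adjusted p = 0.00217), F3H from 14.5 to 46.0 FPKM, TT7 from 2.24 to 12.3 FPKM and CHI (AT3G55120) from 23.9 to 37.2 FPKM. MYBL2 fell from 78.2 to 37.8 FPKM (log2 fold change -1.03, adjusted p = 0.00122). UGT75C1, 5MAT, CHS, F3H, TT7, CHI and MYBL2 were chosen after their values were seen, and each of these 7 calls was kept in the 6 fits that left out 1 library.

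**Figure D2:**
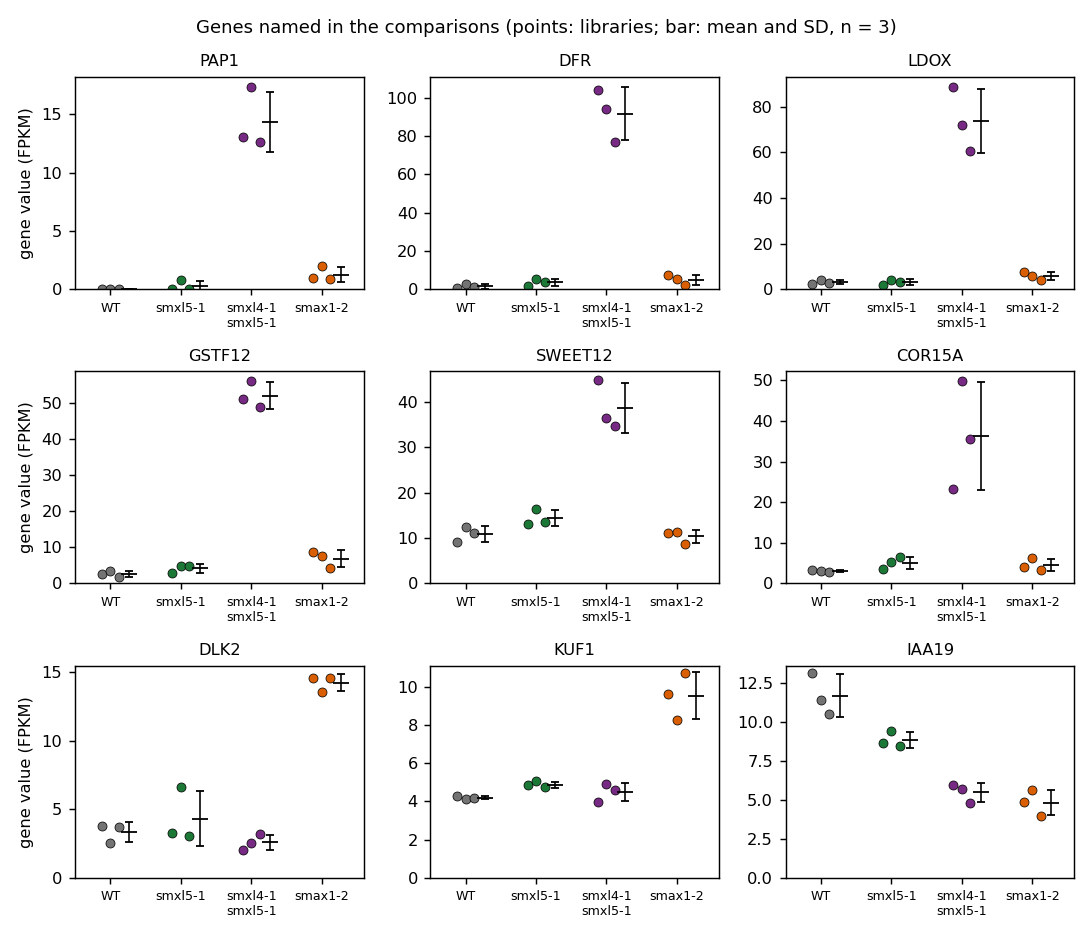
FPKM per library of genes named for the comparisons in the 4 genotypes, with points for libraries and bars for the mean and SD of n = 3. DFR averages 91.6 FPKM in the double mutant and 1.55 FPKM in WT.

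Starch genes were higher in the double mutant as 2 lists. In the synthesis list 3 of 18 genes were called higher (10 adjusted over the list alone). Its median was 0.28 (adjusted p = 2.57e-08, and 0.192 with an estimated correlation). In the breakdown list 4 of 19 were called higher (10 higher and 1 lower adjusted over the list alone). That median was 0.41 (adjusted p = 3.13e-07, and 0.192 with an estimated correlation). APL3, a subunit of the enzyme that makes ADP-glucose, rose from 6.12 ± 0.222 to 17.56 ± 4.13 FPKM (adjusted p = 0.00295), and SBE2.1, a branching enzyme, from 15.4 to 24.4 FPKM. GBSS1, the granule-bound synthase, rose from 35.5 to 73.9 FPKM (adjusted p = 0.048), a call made in none of the 6 fits that left out 1 library (adjusted p = 0.0572 to 0.147). The maltose exporter MEX1 rose from 13.3 to 20.1 FPKM (adjusted p = 0.00168). PWD, SEX4 and PHS2 rose by 0.57, 0.60 and 0.58 on the log2 scale, but PWD stood at -0.083 with the plain sum of FPKM. In the 6 fits that left out 1 library SEX4 was never called (adjusted p = 0.0743 to 0.122), PWD was called only when double-mutant replicate 2 was left out (otherwise 0.0503 to 0.0889) and PHS2 only when double-mutant replicate 3 was (otherwise 0.108 to 0.139).

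Of 15 sugar-starvation genes 3 were called lower in the double mutant (4 adjusted over the list alone). The list median was -0.36 (adjusted p = 3.77e-06, 0.192 with an estimated correlation and 0.0345 with fry). SEN1 fell from 21.2 ± 1.66 to 6.14 ± 3.56 FPKM (log2 fold change -1.74, adjusted p = 0.0144), and was not called without WT replicate 1, 2 or 3 or double-mutant replicate 2 (adjusted p = 0.0509 to 0.0606). AKINBETA1, a subunit of the energy-sensing kinase, fell from 23.9 to 13.8 FPKM (log2 fold change -0.75, adjusted p = 0.00527). With the plain sum of FPKM both turned the other way without being called, SEN1 to 0.44 and AKINBETA1 to 0.23. ASN1, an asparagine synthetase, fell from 8.77 ± 0.706 to 1.98 ± 1.08 FPKM (adjusted p = 0.0218), and was called in 1 of the 6 fits with a library left out, the one without double-mutant replicate 3 (otherwise adjusted p = 0.0639 to 0.0883). Among genes of sucrose metabolism and sugar transport, which were not called as a list (3 of 18 higher and 1 lower, 5 and 3 adjusted over the list alone, median 0.23, adjusted p = 0.293), the sucrose synthase SUS3 rose from 1.03 ± 0.189 to 4.81 ± 0.0781 FPKM (adjusted p = 0.00245). SWEET12 rose from 10.9 ± 1.72 to 38.7 ± 5.49 FPKM (log2 fold change 1.74, adjusted p = 0.000249). It was the 1 called gene of 21 in the phloem list (2 higher and 2 lower adjusted over the list alone), whose median was 0.02 and whose test pointed down (adjusted p = 0.887). SUC2, the companion-cell sucrose carrier, averaged 27.1 FPKM against 40.0 FPKM in WT (adjusted p = 0.108).

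Dehydration and abscisic acid genes were higher in the double mutant, 5 of 18 called (11 adjusted over the list alone). Their median was 0.80 (adjusted p = 1.17e-08, and 0.192 with an estimated correlation). COR15A rose from 3.11 ± 0.284 to 36.3 ± 13.3 FPKM (log2 fold change 3.12, adjusted p = 0.000387), RD20 from 2.98 to 16.1 FPKM (adjusted p = 0.00206) and P5CS1, of proline synthesis, from 16.6 ± 1.45 to 65.5 ± 11.4 FPKM (adjusted p = 0.0219). P5CS1 was chosen after its values were seen. Of the 6 fits with a library left out only the one without double-mutant replicate 1 called it (otherwise adjusted p = 0.0663 to 0.0883). Jasmonate genes were higher, 5 of 16 called (5 adjusted over the list alone). This list's median was 0.24 (adjusted p = 0.0054, and 0.328 with an estimated correlation). LOX2 rose from 46.4 ± 4.68 to 119 ± 29.3 FPKM (adjusted p = 0.00666) and AOC2 from 51.7 ± 6.03 to 129 ± 29.2 FPKM (adjusted p = 0.00773), both enzymes of jasmonate synthesis. Iron-deficiency genes were higher, 2 of 14 called (11 adjusted over the list alone). Here the median was 0.86 (adjusted p = 1.39e-08, and 0.192 with an estimated correlation). NAS4, a nicotianamine synthase, rose from 21.3 to 44.2 ± 13.2 FPKM (adjusted p = 0.0147, and 0.0677 without WT replicate 1). The iron transporter IRT1 rose from 71.4 ± 17.7 to 153 ± 24.7 FPKM (adjusted p = 0.0397), and was called in 1 of the 6 fits with a library left out, the one without WT replicate 2 (otherwise adjusted p = 0.0859 to 0.123).

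Nitrate-response genes were lower in the double mutant as a list, with a median of -0.18 and none of 12 called singly (adjusted p = 0.000104, and adjusted p = 0.296 with an estimated correlation), for example NIA1 at 55.2 FPKM against 85.6 FPKM in WT. Salicylic acid and defence genes were lower, 1 of 9 called (3 adjusted over the list alone). The set median was -0.39 (adjusted p = 0.0054, and 0.164 with an estimated correlation). Photosynthesis genes were lower by a median of -0.17 with none of 23 called (adjusted p = 0.00138, and 0.399 with an estimated correlation). That list was not called with quantile normalization (0.943) or without WT replicate 1 (0.087). The SMXL family was higher (median 0.36, adjusted p = 0.0151, and 0.328 with an estimated correlation). Of 7 genes the mutated SMXL5 alone was called (2 adjusted over the list alone). The list was not called without double-mutant replicate 1 (0.0579) or a filter (0.0649). IAA19, an auxin-response repressor, fell from 11.7 ± 1.35 to 5.47 ± 0.618 FPKM (log2 fold change -0.97, adjusted p = 0.00345) and was the 1 called gene of 25 in the auxin list, whose median was 0.08 while its mean and test pointed down (adjusted p = 0.439). BBX32, a B-box protein of light signalling, rose from 3.996 to 7.24 FPKM (adjusted p = 0.00675). Phosphate-starvation genes had a median of 0.083 with none of 18 called (adjusted p = 0.421).

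Among the largest changes outside these lists in the double mutant, AT2G16367 rose from 6.16 ± 5.47 to 140 ± 33.6 FPKM (log2 fold change 4.88, adjusted p = 0.00773), and the peroxidase gene PER23 fell from 40.0 ± 6.79 to 3.11 ± 0.711 FPKM (log2 fold change -3.32, adjusted p = 0.000463). HEI10, a ligase of meiotic crossovers that overlaps MRD1 on chromosome 1, was unlisted in the double mutant and stood at 13.7, 16.6 and 16.7 FPKM in WT (adjusted p = 1.17e-05). AT3G55605 (12.8, 15.2 and 13.9 FPKM in WT, adjusted p = 5.03e-06) and AT5G27500 (14.7, 11.2 and 15.8 FPKM in WT, adjusted p = 5.03e-06) were also unlisted there. AT5G18661 (11.9, 12.1 and 21.6 FPKM in WT, adjusted p = 0.00206) was too, a difference of -14.17 estimated fragments. AT2G39795 was unlisted there too, at 20.5, 22.2 and 24.7 FPKM in WT (adjusted p = 0.0397). It was called in none of the 6 fits with 1 library out (0.0977 to 0.118). AT2G39795 was unlisted in smxl5-1 replicate 2 as well, where its adjacent gene P5CS1 stood at 66.9 FPKM against 22.9 and 26.2 FPKM in replicates 1 and 3. In estimated fragments of the double mutant against WT, AT2G39795 differed by -365.8 and P5CS1 by 2966. Fragments of AT2G39795 assembled into a piece of P5CS1 are therefore not excluded. The circadian clock (median 0.24, adjusted p = 0.0796), heat shock (-0.22, adjusted p = 0.106), RNA silencing (0.12, adjusted p = 0.204), light and hypocotyl growth (0.04, adjusted p = 0.461) and xylem and cambium (0.09, adjusted p = 0.887) lists were not called by camera here or in the other 4 comparisons. With fry the light and hypocotyl list was called higher in the double mutant against WT (adjusted p = 0.048) and smax1-2 (0.00922). Root hair genes (0.25, adjusted p = 0.387), cell cycle genes (0.02, adjusted p = 0.887) and cytokinin genes (-0.03, adjusted p = 0.0928) were not called in the double mutant against WT. SESA2 was the only seed storage gene tested, so that list had no set test. SESA2 was unlisted in WT and averaged 5.26 ± 5.12 FPKM in the double mutant (adjusted p = 0.107). Among the 48 calls named by rule or as shared in this comparison 30 were kept in each fit that left out 1 library, and 10 in every fit run. In smxl5-1 it was 8 and 0 of 17 and in smax1-2 7 and 0 of 14. In the double mutant it was 28 and 6 of 61 against smxl5-1 and 23 and 6 of 50 against smax1-2.

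**Figure D3:**
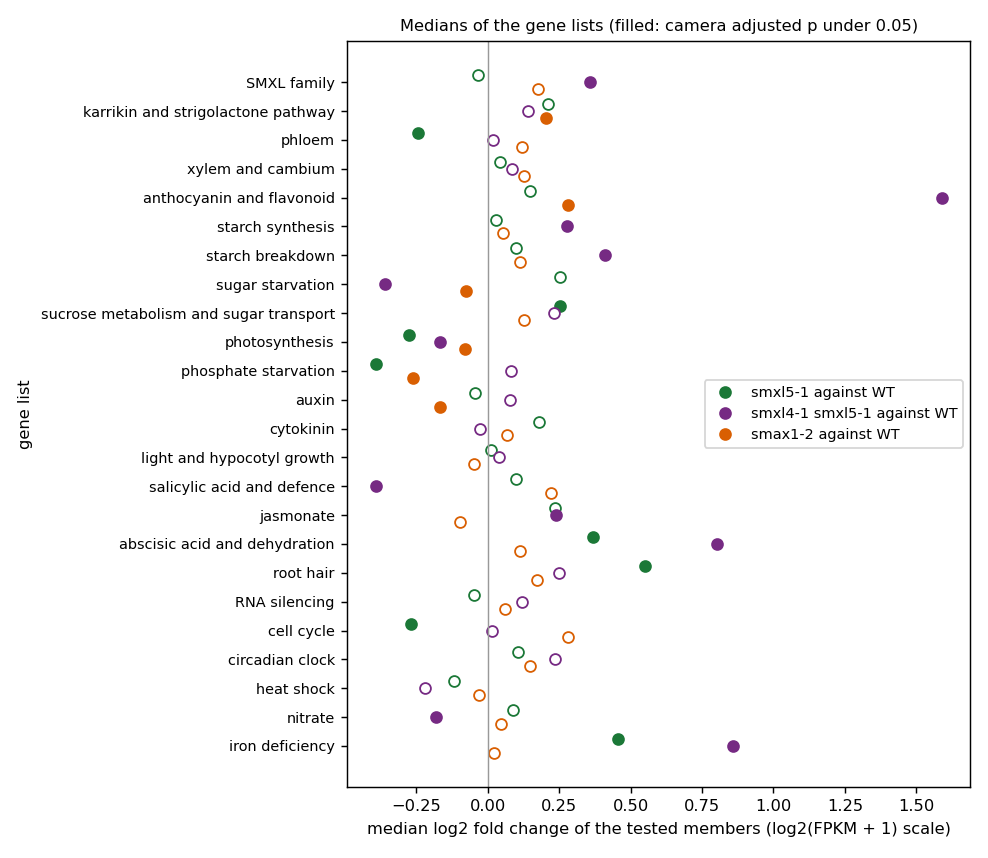
Median log2 fold change of the tested genes of each list in the 3 mutants against WT, filled where camera called the list at the preset correlation. The anthocyanin and flavonoid list lies at 1.59 in the double mutant, 0.15 in smxl5-1 and 0.28 in smax1-2.

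In smxl5-1 several genes were listed that were unlisted in every other library, among them the nitrilase gene NIT2 and the chitinase-like gene AT4G01700. Single genes of several lists rose, among them BAM5, a beta-amylase, GPT2, a plastid carrier of glucose phosphate, and STP13, a hexose carrier. The starch breakdown (1 of 19 called, adjusted p = 0.281) and starch synthesis (1 of 18 called, adjusted p = 0.45) lists were not called. The defence gene PR4 rose. HEI10 and MRD1, which overlap each other, fell to 0 or near it. Against WT, 145 genes were called, 109 higher and 36 lower, while 2960 had an unadjusted p under 0.05. In each of the 145 the libraries of the groups did not overlap, which was so for 20.4% of the tested genes, where chance gives 10%. The share of higher calls was 75.2%, but 49.6% of 141 calls with quantile normalization and 53.8% of 130 with median-of-ratios scaling. The count was 30 or 41 without WT replicate 1 or 2, and 78 or 70 without smxl5-1 replicate 1 or 3. The absolute log2 fold change was at least 1 in 60 of them, and 13 were unlisted in every library of one group.

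NIT2 stood at 74.98, 104 and 79.8 FPKM in smxl5-1 (adjusted p = 9.15e-09) and AT4G01700 at 34.3, 30.9 and 44.9 FPKM (adjusted p = 1.24e-07), both unlisted in the other 9 libraries, as was AT3G63510 (13.1, 5.15 and 8.73 FPKM, adjusted p = 0.000479). In estimated fragments against WT, AT4G01700 differed by 594.3 and its adjacent gene AT4G01690 by -791.7, so a change of assembly is not excluded. For NIT2 it was 2244, with 6027 for its adjacent gene AT3G44310. For AT3G63510 it was 227.3, with -7.856 for its adjacent gene AT3G63520. HEI10 fell from 15.7 ± 1.67 to 0.416 ± 0.504 FPKM (log2 fold change -3.61, adjusted p = 2.45e-05). MRD1 stood at 7.61, 5.95 and 8.08 FPKM in WT and was unlisted in smxl5-1 (adjusted p = 2.45e-05). AT5G27500 (adjusted p = 3.85e-06) and AT5G18661 (adjusted p = 0.00652) were unlisted in smxl5-1, as in the double mutant. AT2G07811, listed at 11.1, 13.8 and 10.5 FPKM in WT and at 0 in smxl5-1 (adjusted p = 0.012), was not called without WT replicate 1 (0.0551) or 2 (0.0562). BAM5 rose from 0.304 ± 0.302 to 6.28 ± 1.44 FPKM (log2 fold change 2.49, adjusted p = 0.0152), but not without WT replicate 1 (0.0702) or smxl5-1 replicate 1 (0.0566). GPT2 rose from 2.39 ± 1.17 to 16.4 ± 7.97 FPKM (adjusted p = 0.0345), which held in 1 of the 6 fits with a library left out, the one without smxl5-1 replicate 2 (otherwise adjusted p = 0.0616 to 0.121). STP13 rose from 4.70 ± 0.497 to 10.8 ± 1.05 FPKM (adjusted p = 0.0138, and 0.0702 without WT replicate 1), and PR4 from 109 ± 4.79 to 198 ± 15.1 FPKM (adjusted p = 0.012, and 0.0551 without WT replicate 1). ABI1, a phosphatase of abscisic acid signalling, rose from 18.7 ± 0.988 to 29.5 ± 4.88 FPKM (adjusted p = 0.0358), but not without WT replicate 1, 2 or 3 or smxl5-1 replicate 3 (0.067 to 0.138). AT1G66100 fell from 96.5 ± 13.8 to 31.5 ± 11 FPKM (adjusted p = 0.031), but of the fits with 1 library left out only the one without smxl5-1 replicate 2 called it (otherwise 0.0566 to 0.121).

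Of the 24 lists 8 were called in smxl5-1, 4 higher and 4 lower, and none with an estimated correlation. Phloem genes were lower, with a median of -0.24 and none of 21 called singly (adjusted p = 2.36e-05, and adjusted p = 0.454 with an estimated correlation), for example SUC2 at 27.5 ± 6.19 FPKM against 40.0 ± 2.44 FPKM in WT (adjusted p = 0.131). Photosynthesis genes had a median of -0.27 with none of 23 called (6 lower adjusted over the list alone, adjusted p = 3.92e-10, and adjusted p = 0.454 with an estimated correlation), but adjusted p = 0.151 with quantile normalization. Phosphate-starvation genes had a median of -0.39 (none of 18 called, 1 higher and 3 lower adjusted over the list alone, adjusted p = 0.00152, and adjusted p = 0.714 with an estimated correlation), and were not called without WT replicate 1 (0.089). Iron-deficiency genes had a median of 0.46 with none of 14 called (adjusted p = 0.00153, and adjusted p = 0.714 with an estimated correlation), for example IRT1 at 126 ± 41.3 FPKM against 71.4 ± 17.7 FPKM. Abscisic acid and dehydration genes had a median of 0.37 with 1 of 18 called (8 adjusted over the list alone, adjusted p = 0.00876, and adjusted p = 0.714 with an estimated correlation). Root hair genes (median 0.55, none of 10 called, adjusted p = 0.00876) and genes of sucrose metabolism and sugar transport (median 0.25, 1 of 18 called, 3 adjusted over the list alone, adjusted p = 0.0334) were higher, and cell cycle genes (median -0.27, none of 7 called, adjusted p = 0.0384) were lower, each with adjusted p = 0.714 with an estimated correlation. The cell cycle list was not called with quantile normalization (0.0502), and the root hair (0.0671) and sugar transport (0.0892) lists not with the stricter filter. Without WT replicate 2 the root hair, sugar transport and cell cycle lists were not called (0.0934 each). Without WT replicate 3 the iron, abscisic acid, root hair and sugar transport lists (0.0516 each) and the cell cycle list (0.097) were not called. Without smxl5-1 replicate 2 the abscisic acid (0.117), root hair (0.365), sugar transport (0.674) and cell cycle (0.729) lists were not called, and the number of lists called was 5 without WT replicate 2 and 3 without WT replicate 3.

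In smax1-2 the karrikin-response genes DLK2 and KUF1 rose, and IAA19 fell. ARR15, a cytokinin-response regulator, and ABCG22, a transporter, rose, and RGF6, a root growth peptide, fell. AT5G57700, which lies next to SMAX1, rose. Against WT 16 genes were called, 10 higher and 6 lower, while 1338 had an unadjusted p under 0.05. In all 16 the libraries of the groups did not overlap, which was so for 17.41% of the tested genes, where chance gives 10%. The share of higher calls was 62.5%, but 45.5% of 22 calls with quantile normalization and 47.6% of 21 with median-of-ratios scaling. Each of the 16 was among both of these sets.

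KUF1 rose from 4.21 ± 0.0904 to 9.55 ± 1.24 FPKM (log2 fold change 1.01, adjusted p = 0.00854) and AT5G57700 from 14.1 ± 0.13 to 23.9 ± 0.824 FPKM (adjusted p = 0.00938). DLK2 rose from 3.34 ± 0.72 to 14.3 ± 0.596 FPKM (log2 fold change 1.83, adjusted p = 0.0232), but was called in none of the 6 fits with 1 library out (0.0599 to 0.105). ABCG22 rose from 9.69 ± 0.923 to 29.7 ± 6.24 FPKM (adjusted p = 0.0271), and of those fits only the one without smax1-2 replicate 2 called it (otherwise 0.0752 to 0.131). AT3G60290 rose from 4.16 to 13.1 FPKM (adjusted p = 0.0344), and ARR15, unlisted in WT, stood at 3.98, 4.91 and 2.91 FPKM (adjusted p = 0.0344), and neither was called in any fit that left out 1 of the 6 libraries (0.0779 to 0.17 and 0.066 to 0.131). AT4G14020 rose from 36.8 ± 2.3 to 71.3 ± 10.6 FPKM (adjusted p = 0.0219), but not without WT replicate 1, 2 or 3 or smax1-2 replicate 1 (0.0511 to 0.105). IAA19 fell from 11.7 ± 1.35 to 4.82 ± 0.819 FPKM (log2 fold change -1.13, adjusted p = 0.00938). RGF6 fell from 43.3 ± 7.98 to 18.6 ± 3.58 FPKM (log2 fold change -1.18, adjusted p = 0.0344), but not without WT replicate 1 or 2 or smax1-2 replicate 2 or 3 (0.114 to 0.17). AT5G27500 (adjusted p = 1.15e-05) was unlisted in smax1-2. So were the microRNA gene MIR171B (4.45, 4.80 and 4.51 FPKM in WT) and AT3G01329 (4.15, 5.03 and 4.67 FPKM in WT). Both (adjusted p = 0.000424), chosen after their values were seen, differed by -16.35 and -11.16 estimated fragments. AT2G27420 fell from 19.2 ± 2.61 to 10.6 ± 1.45 FPKM (adjusted p = 0.0344), but was called in none of the 6 fits with 1 library out (0.0511 to 0.123).

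Of the 24 lists 6 were called in smax1-2, and none with an estimated correlation. The karrikin and strigolactone list was higher, 2 of 10 called (3 adjusted over the list alone), with a median of 0.20 (adjusted p = 0.00201, and adjusted p = 0.349 with an estimated correlation), for example BBX20 at 4.05 FPKM against 0.947 FPKM in WT (adjusted p = 0.251). Auxin genes were lower, 1 of 25 called (3 adjusted over the list alone), with a median of -0.17 (adjusted p = 4.52e-08, and adjusted p = 0.218 with an estimated correlation), for example IAA1 at 6.47 FPKM against 12.8 FPKM (adjusted p = 0.068). Anthocyanin genes were higher with none of 17 called (3 adjusted over the list alone) and a median of 0.28 (adjusted p = 8.42e-05, and adjusted p = 0.218 with an estimated correlation). Phosphate-starvation genes had a median of -0.26 with none of 18 called (adjusted p = 0.00211, and adjusted p = 0.624 with an estimated correlation), and were not called without WT replicate 1 (0.404) or smax1-2 replicate 2 (0.0762). Photosynthesis genes had a median of -0.08 with none of 23 called (adjusted p = 0.00123, and adjusted p = 0.601 with an estimated correlation), but were not called without WT replicate 1 (0.275) or smax1-2 replicate 3 (0.0978), and with quantile normalization the median was 1.78e-15 (adjusted p = 0.8). Sugar-starvation genes had a median of -0.08 with none of 15 called (adjusted p = 0.00707, and adjusted p = 0.601 with an estimated correlation), and were not called without WT replicate 3 (0.085) or smax1-2 replicate 2 (0.287), nor with the exact-match covariate (median 0.0258, adjusted p = 0.107).

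Against smxl5-1, the double mutant again had the anthocyanin genes higher and MYBL2 lower. The sugar-starvation genes SEN1 and DIN10 and the hexose carrier STP1 were lower, and the defence gene PR4 was lower. SWEET11 and SWEET12, both sucrose exporters of the leaf phloem, were higher. NIT2 and AT4G01700, listed only in smxl5-1, were lower, by -2244 and -594.3 estimated fragments. Their adjacent genes AT3G44310 and AT4G01690 moved the other way, by 2956 and 1265 fragments, so a change of assembly is not excluded. In this test of the difference between the 2 mutants 1315 genes were called, 565 higher and 750 lower in the double mutant, while 4292 had an unadjusted p under 0.05. In each of the 1315 the libraries of the groups did not overlap, which was so for 24.4% of the tested genes, where chance gives 10%. The count was 731 or 759 without smxl5-1 replicate 1 or 3, and 824 or 453 without double-mutant replicate 2 or 3. The absolute log2 fold change was at least 1 in 304. The share of higher calls was 43.0%, but 52.8% of 1372 calls with quantile normalization and 46.8% of 1305 with median-of-ratios scaling.

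Of the anthocyanin list 12 of 17 were higher and 1 lower (14 and 1 adjusted over the list alone), with a median of 1.49 (adjusted p = 3.24e-16, and adjusted p = 0.0119 with an estimated correlation), DFR at 91.6 against 3.58 FPKM (log2 fold change 4.41, adjusted p = 0.000624) and LDOX at 73.7 against 3.08 FPKM (adjusted p = 0.000119). MYBL2, again chosen after its values were seen, was at 37.8 against 92.6 FPKM (log2 fold change -1.27, adjusted p = 0.00034). Phloem genes were higher, 5 of 21 called (6 adjusted over the list alone), with a median of 0.18 (adjusted p = 0.00118, and adjusted p = 0.37 with an estimated correlation). SWEET12 was at 38.7 against 14.4 FPKM (adjusted p = 0.00123) and SWEET11 at 127 ± 16.6 against 73.4 ± 7.45 FPKM (adjusted p = 0.0055). CLE41, a peptide that acts on the cambium, was at 31.7 against 20.9 FPKM (adjusted p = 0.0283), but not called without smxl5-1 replicate 2 or 3 or double-mutant replicate 2 or 3 (0.0572 to 0.106). Sugar-starvation genes were lower, 5 of 15 called (1 higher and 12 lower adjusted over the list alone), with a median of -0.79 (adjusted p = 4.16e-07, and adjusted p = 0.267 with an estimated correlation). SEN1 was at 6.14 against 35.1 FPKM (log2 fold change -2.41, adjusted p = 0.00261), AKINBETA1 at 13.8 against 24.98 FPKM (adjusted p = 0.00303) and DIN10 at 44.9 against 105 FPKM (adjusted p = 0.0186, but 0.0524 without smxl5-1 replicate 3 and 0.0732 without double-mutant replicate 3). Genes of sucrose metabolism and sugar transport went both ways, 3 higher and 3 lower of 18 (4 and 8 adjusted over the list alone, median -0.04, adjusted p = 0.61), with STP1 at 18.3 against 42.0 FPKM (adjusted p = 0.0039).

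Starch synthesis genes were higher in the double mutant than in smxl5-1, 4 of 18 called (8 adjusted over the list alone, median 0.27, adjusted p = 0.000146, and adjusted p = 0.453 with an estimated correlation), with GBSS1 at 73.9 against 31.3 FPKM (adjusted p = 0.0151) and PGM1, the plastid phosphoglucomutase, at 41.3 against 30.9 FPKM (adjusted p = 0.011), though at -0.29 on the log2 scale with the plain sum of FPKM. Starch breakdown genes were higher, 3 of 19 called and 1 lower (6 and 1 adjusted over the list alone, median 0.25, adjusted p = 0.000597, and adjusted p = 0.453 with an estimated correlation), with BAM5 the lower one at 0.779 against 6.28 FPKM (log2 fold change -2.11, adjusted p = 0.0101). MEX1 was higher by 0.46 on the log2 scale (adjusted p = 0.0039) and stood at -0.33 with the plain sum of FPKM. Dehydration genes (4 of 18 higher and 1 lower, 9 and 2 adjusted over the list alone, median 0.53, adjusted p = 0.00118, and adjusted p = 0.455 with an estimated correlation) and phosphate-starvation genes (1 of 18 higher, 6 adjusted over the list alone, median 0.54, adjusted p = 0.00101, and adjusted p = 0.525 with an estimated correlation) were higher. Photosynthesis genes were higher with 1 of 23 called (1 adjusted over the list alone, median 0.12, adjusted p = 0.00875, and adjusted p = 0.572 with an estimated correlation), but not with quantile normalization (adjusted p = 0.246). Iron-deficiency genes were higher with 1 of 14 called (2 adjusted over the list alone, median 0.24, adjusted p = 0.0188, and adjusted p = 0.572 with an estimated correlation), but not without double-mutant replicate 1 (adjusted p = 0.956), or without it and smxl5-1 replicate 2 (adjusted p = 0.442). Cytokinin genes (2 of 13 lower, 5 adjusted over the list alone, median -0.40, adjusted p = 0.00576, and adjusted p = 0.267 with an estimated correlation) and nitrate genes (2 of 12 lower, 3 adjusted over the list alone, median -0.37, adjusted p = 0.00118, and adjusted p = 0.453 with an estimated correlation) were lower. ARR6 was at 13.5 against 20.1 FPKM (adjusted p = 0.0125), but at a log2 fold change of 0.025 with classes =, c and j alone. The nitrate-response regulator HRS1 was at 7.93 against 17.5 FPKM (adjusted p = 0.00908). Salicylic acid and defence genes were lower, 2 of 9 called (1 higher and 3 lower adjusted over the list alone, median -0.33, adjusted p = 0.036, and adjusted p = 0.267 with an estimated correlation), but not without double-mutant replicate 2 (adjusted p = 0.101), without a filter (0.0678), with the stricter filter (0.054) or with a block of the replicate numbers (0.0522). With the stricter filter the dehydration list was not called either (0.0606), nor the phosphate list (0.0557) without smxl5-1 replicate 2 and double-mutant replicate 1, the 2 libraries with the most exact-match pieces. PR4 was at 77.9 against 198 FPKM (log2 fold change -1.34, adjusted p = 0.00024). COR15A was higher by 2.59 on the log2 scale (adjusted p = 0.00141). The light and hypocotyl list went both ways, with 2 of 20 called higher and 2 lower (4 and 2 adjusted over the list alone, median -0.04, adjusted p = 0.978). BBX31 and BBX32 were higher by 1.19 (adjusted p = 0.00695) and 0.80 (adjusted p = 0.00342) on the log2 scale. BBX21 was at 38.8 against 57.3 FPKM (adjusted p = 0.0174) and BBX22 at 23.7 against 32.6 FPKM (adjusted p = 0.0163).

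The largest other differences between the double mutant and smxl5-1 include AT3G58980 at 32.0 ± 7.72 against 0.137 FPKM (log2 fold change 4.85, adjusted p = 0.0174), which was not called without smxl5-1 replicate 1 (0.051) or double-mutant replicate 3 (0.0534). The histone gene HTR11 was at 107 ± 28.5 against 3.78 ± 1.5 FPKM (adjusted p = 0.0236), and of the fits with 1 library left out only the one without double-mutant replicate 1 called it (otherwise 0.0552 to 0.0756). HTR11 stood at 93.0, 3.59 and 113 FPKM in WT, so it varied as widely within that genotype. AT3G58980 also varied within a genotype, at 26.0, 0.677 and 0.447 FPKM in smax1-2. AT3G55605 was unlisted in the double mutant and stood at 16.1, 10.096 and 18.4 FPKM in smxl5-1 (adjusted p = 4.47e-06). AT2G31725 was unlisted in smxl5-1 and stood at 15.5, 21.8 and 20.1 FPKM in the double mutant (adjusted p = 0.0462). AT5G53048 was unlisted in smxl5-1 and stood at 15.6, 19.4 and 11.2 FPKM (adjusted p = 0.0352). Neither was called in any of the 6 fits that left out 1 library (0.0781 to 0.129 and 0.0691 to 0.0929). Each was also listed in 1 WT library, AT2G31725 at 15.2 FPKM and AT5G53048 at 8.58 FPKM. The double mutant listed none of AT5G03285 (49.7, 28.8 and 45.5 FPKM in smxl5-1, adjusted p = 0.0193), AT4G00670 (20.6, 26.5 and 23.6 FPKM, adjusted p = 0.0192) and AT1G19710 (10.5, 11.1 and 11.2 FPKM, adjusted p = 0.0172). AT5G03285 and AT4G00670 were not called without smxl5-1 replicate 1 or 3 or double-mutant replicate 2 or 3 (0.0516 to 0.0674 and 0.0505 to 0.0669). AT1G19710 was not called without double-mutant replicate 3 (0.0601). D27, an enzyme of strigolactone synthesis, was at 8.85 against 5.47 FPKM (adjusted p = 0.0121).

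Against smax1-2, the double mutant had the anthocyanin genes, SWEET12 and COR15A higher. DLK2 and KUF1, the karrikin-response genes, were lower. Single genes of the jasmonate list (5 of 16) were higher and single genes of the defence list (3 of 9), such as PR4, lower, though neither list was called with an estimated correlation (adjusted p = 0.142 and 0.0911). BBX31 and BBX32 were higher. In this test of the difference 546 genes were called, 285 higher and 261 lower, while 2771 had an unadjusted p under 0.05. In each of the 546 the libraries of the groups did not overlap, which was so for 21.2% of the tested genes, where chance gives 10%. The count was 343 or 297 without double-mutant replicate 1 or 3, and 259, 346 or 274 without smax1-2 replicate 1, 2 or 3. The absolute log2 fold change was at least 1 in 218, and 52.2% of the calls were higher.

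DLK2 was at 2.58 ± 0.58 FPKM in the double mutant against 14.3 FPKM in smax1-2 (log2 fold change -2.10, adjusted p = 0.00122) and at 0.022 with the plain sum of FPKM. KUF1 was at 4.50 against 9.55 FPKM (log2 fold change -0.94, adjusted p = 0.00141). These were the 2 called genes of 10 in the karrikin and strigolactone list (2 higher and 3 lower adjusted over the list alone), which was not called (median -0.02, adjusted p = 0.359). Of the anthocyanin list 12 of 17 were higher and 1 lower (13 and 1 adjusted over the list alone, median 1.31, adjusted p = 1.76e-18, and adjusted p = 0.00766 with an estimated correlation), with DFR at 91.6 against 4.93 FPKM (log2 fold change 4.07, adjusted p = 0.000966), LDOX at 73.7 against 5.84 FPKM (adjusted p = 0.000251) and UGT79B1 at 20.8 against 1.63 FPKM (adjusted p = 0.00385). PAP1, at 14.3 against 1.26 FPKM (adjusted p = 0.000608), and MYBL2, lower by a log2 fold change of -1.19 (adjusted p = 0.000432), were chosen after their values were seen. SWEET12 was at 38.7 against 10.4 FPKM (log2 fold change 1.80, adjusted p = 0.000251). CLE5, a signalling peptide gene, was unlisted in smax1-2 and stood at 16.3, 9.28 and 10.98 FPKM in the double mutant (adjusted p = 0.000695), and GRXS10 was unlisted in smax1-2 and stood at 9.11, 8.18 and 12.2 FPKM (adjusted p = 0.00427). HEI10 was unlisted in the double mutant and stood at 15.9, 16.0 and 17.8 FPKM in smax1-2 (adjusted p = 1.3e-05). AT5G18661 was too, at 47.2, 46.1 and 10.6 FPKM in smax1-2 (adjusted p = 0.000567), a difference of -14.92 estimated fragments. The double mutant also listed none of AT5G03285 (48.2, 33.9 and 42.4 FPKM in smax1-2, adjusted p = 0.029), AT3G26460 (39.6, 38.9 and 26.95 FPKM, adjusted p = 0.0382), AT4G00670 (21.9, 26.5 and 36.3 FPKM, adjusted p = 0.0241) and AT2G39795 (21.9, 23.5 and 23.4 FPKM, adjusted p = 0.0341). AT2G16367 was at 140 ± 33.6 against 13.3 ± 4.15 FPKM (log2 fold change 3.32, adjusted p = 0.0418). These last 5 genes were called in none of the 6 fits with 1 library out (0.0671 to 0.126). AT3G26460 was also unlisted in smxl5-1, and stood at 0, 37.1 and 38.0 FPKM in WT. IAA1 was at 12.8 against 6.47 FPKM (log2 fold change 0.88, adjusted p = 0.00864), in an auxin list that was higher with 2 of 25 called (5 adjusted over the list alone, median 0.26, adjusted p = 0.000889, and adjusted p = 0.263 with an estimated correlation). SMAX1 itself was at 28.2 against 16.9 FPKM (adjusted p = 0.031), and of the fits with 1 library left out only the one without double-mutant replicate 2 called it (otherwise 0.071 to 0.102).

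Dehydration genes were higher in the double mutant than in smax1-2 with 5 of 18 called (11 adjusted over the list alone, median 0.94, adjusted p = 1.88e-10, and adjusted p = 0.14 with an estimated correlation), COR15A by 2.72 and RD20 by 1.88 on the log2 scale. Iron-deficiency genes were higher with 1 of 14 called (13 adjusted over the list alone, median 0.83, adjusted p = 1.55e-09, and adjusted p = 0.14 with an estimated correlation), NAS4 at 44.2 against 19.0 FPKM (adjusted p = 0.00633). Jasmonate genes were higher with 5 of 16 called (5 higher and 1 lower adjusted over the list alone, median 0.58, adjusted p = 1.16e-05, and adjusted p = 0.142 with an estimated correlation). Starch synthesis genes (3 of 18 higher, 10 adjusted over the list alone, median 0.31, adjusted p = 3.72e-08) and starch breakdown genes (2 of 19 higher, 6 adjusted over the list alone, median 0.32, adjusted p = 7.54e-08) were higher, each with adjusted p = 0.142 with an estimated correlation. APL3 was higher by 1.15 on the log2 scale (adjusted p = 0.00643). Phosphate-starvation genes were higher with none of 18 called (4 adjusted over the list alone, median 0.38, adjusted p = 0.00165, and adjusted p = 0.445 with an estimated correlation). Salicylic acid and defence genes were lower with 3 of 9 called (5 adjusted over the list alone, median -0.86, adjusted p = 0.00145, and adjusted p = 0.0911 with an estimated correlation), PR4 by a log2 fold change of -0.88 (adjusted p = 0.00253). Cytokinin genes (2 of 13 lower, 3 adjusted over the list alone, median -0.33, adjusted p = 0.00153, and adjusted p = 0.14 with an estimated correlation) and nitrate genes (1 of 12 lower, 4 adjusted over the list alone, median -0.30, adjusted p = 0.000465, and adjusted p = 0.275 with an estimated correlation) were lower. Sugar-starvation genes were lower with 2 of 15 called (1 higher and 4 lower adjusted over the list alone, median -0.32, adjusted p = 0.00772, and adjusted p = 0.414 with an estimated correlation), but not without smax1-2 replicate 3 (0.0505). The SMXL family was higher (median 0.42, adjusted p = 0.0453, and 0.414 with an estimated correlation). Of 7 genes SMAX1 alone was called (2 adjusted over the list alone). The list was not called without double-mutant replicate 1 (0.0989) or 3 (0.162) or smax1-2 replicate 3 (0.101). Nor was it with no filter (0.227), the stricter filter (0.139), the exact-match covariate (0.0871) or without both libraries with the most exact-match pieces (0.103). BBX31 was at 18.4 against 6.64 FPKM (adjusted p = 0.00385), and BBX32 was higher by 1.00 on the log2 scale (adjusted p = 0.000966). These were the 2 called genes of 20 in the light and hypocotyl list.

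The double mutant and smax1-2 shared 5 genes called in the same direction against WT, AT5G35935 higher and IAA19, MIR171B, AT3G01329 and AT5G27500 lower. Of these IAA19 alone was not also called in smxl5-1 against WT, where the other 4 changed in the same direction. AT2G27420 rose in the double mutant (adjusted p = 0.00467) and fell in smax1-2 (0.0344, but in none of the 6 fits with 1 library out). AT5G35935, MIR171B and AT3G01329, and AT2G27420 in the double mutant, were chosen after their values were seen. Independent calls would share 0.145 higher and 0.0613 lower genes. Groups simulated without a change against a shared WT group shared 0.01 on average and at most 1, but have few calls to share, so it decides nothing. Across the 18879 genes, which are not independent replicates, the log2 fold changes had r = 0.38 (rho = 0.32), below the simulated mean of 0.50 (0.45 to 0.54), and a covariance of 0.0744 against a simulated 0.0657 (at most 0.0724). The number shared was 9, 8 or 9 without WT replicate 1, 2 or 3 and 8 without smax1-2 replicate 3, and r was 0.49 without WT replicate 3.

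The double mutant and smxl5-1 shared 36 genes called in the same direction against WT, 21 higher and 15 lower, and 3 went opposite ways. Independent calls would share 1.58 and 0.368. The shared genes include the lower AT1G23130, HEI10 and MRD1 and the metallothionein gene MT3, and the higher CLE5, the histone gene HIS1-3 and the isocitrate lyase gene ICL, chosen after their values were seen. In smxl5-1 ICL was called in none of the 6 fits with 1 library out (0.0715 to 0.143). CLE5 was not called there without WT replicate 1 or 2 or smxl5-1 replicate 1 or 3 (0.0993 to 0.137), MT3 not without WT replicate 1 or 2 (0.0772 and 0.0626) and HIS1-3 not without WT replicate 1 (0.0547). With the plain sum of FPKM ICL stood at -1.29 in smxl5-1 and at -0.74 in the double mutant. PR4, AT2G27420 and AT5G19230 are the 3 that went opposite ways. PR4 and AT5G19230 were higher in smxl5-1 and lower in the double mutant, and AT2G27420 the reverse. PR4 in the double mutant was called only without replicate 1 of that mutant (otherwise adjusted p = 0.108 to 0.159). In smxl5-1 it was not called without WT replicate 1 (0.0551). In smxl5-1 AT5G19230 was called only without smxl5-1 replicate 3 (otherwise 0.0774 to 0.148). AT2G27420 was not called there without WT replicate 1 or 2 or smxl5-1 replicate 3 (0.0526 to 0.0551). The log2 fold changes had r = 0.38 (rho = 0.23) against the same simulated 0.50, with a covariance of 0.0840 against 0.0657. The simulated groups again shared 0.01 genes on average and at most 1. The 3 WT libraries cannot be split between the comparisons, so part of the excess in either pair may come from the shared controls. The number shared was 14 or 17 without WT replicate 1 or 2, and 22 without smxl5-1 replicate 3.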

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

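The counts in this part were chosen after the values were seen, come with no test of their own, and no explanation was tested for them, technical or biological. They come from transfrags that the comparisons leave out, and each counts genes with such a transfrag in all 3 libraries of a mutant and in no WT library. With no strand given in the sources used here, the strand of these pieces is uncertain.

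Intronic transfrags were listed in this way for 4 genes in smxl4-1 smxl5-1 (AT1G01710, AT1G20090, AT2G42300 and AT3G44370), while 3 genes had them in all WT libraries and in none of that mutant. In smax1-2 the count was 6 genes (AT1G01490, AT1G32240, AT2G35060, AT3G53270, AT4G02590 and AT5G47310), against 2 the other way. Antisense transfrags were listed for 2 genes in smxl4-1 smxl5-1 (AT1G75940 and AT4G14660), against 0 the other way. Run-on transfrags, which lie just beyond a gene, were listed for 4 genes in smxl5-1 (AT1G02880, AT1G36630, AT2G35460 and AT3G17090), against 1 the other way, and for 5 genes in smax1-2 (AT1G02880, AT2G27315, AT3G15130, AT3G29755 and AT5G18360), against 3 the other way. In smxl4-1 smxl5-1 the run-on counts were 5 genes (AT1G01700, AT1G02880, AT2G35460, AT4G08020 and AT5G39040) against 6 the other way, so these counts go both ways. In smxl5-1 the intronic count went the other way, with 1 gene in all 3 mutant libraries only and 6 in all 3 WT libraries only.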

How the results depend on the processing

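The tests with a block by file-name number, median-of-ratios scaling, classes =, c and j, the other gene-value definitions, genes listed in all 12 libraries, the exact-match covariate, the robust fit, both high exact-match libraries out and voom were chosen only after the results were seen. The planned DESeq2 Wald test and voom needed counts and were not run, and voom was run on estimated fragments only. Because depth per gene is estimated, a gene near the lowest listed FPKM of a library (0.366 to 0.665) cannot be told from one not assembled. The numbers of the titles did not pair libraries (0 of 18 correlations of residuals above 0.1), and those of the file names, which swap replicates 1 and 2 of the double mutant, gave 2 of 18.

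Counts are given in the order smxl5-1, double mutant and smax1-2 against WT, then double mutant against smxl5-1 and against smax1-2. At adjusted p under 0.01 they were 21, 161, 8, 273 and 186, with 8 shared by the double mutant and smxl5-1, and with an absolute log2 fold change of at least 1 they were 60, 191, 13, 304 and 218, with 18 shared, both by construction. The plain sum of FPKM gave 9, 58, 5, 80 and 77, and plain length 67, 222, 7, 634 and 309, where the spread within groups was wider. The exact-match covariate gave 539, 831, 2100 and 825 for all but smax1-2 against WT, and classes =, c and j gave 82, 310 and 10 for the 3 against WT. The stricter filter gave 9 in smax1-2 and 2 shared with the double mutant. The title block gave 59, 7, 769 and 363 for all but the double mutant against WT, with 22 shared by the double mutant and smxl5-1, and the file-name block 57 in smxl5-1 and 10 in smax1-2. Only the 2 groups compared gave 51 in smxl5-1, and 187 and 348 for the last 2, with fewer libraries for the spread. In smxl5-1 no limit on transfrag length gave 224 and genes listed in all 12 libraries 262. Without both high exact-match libraries counts were 182, 558, 26, 1076 and 541, with 98, 345, 14, 775 and 399 main calls kept. Voom gave 7 in smax1-2. Causes not given were not tested.

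Lists called numbered 0, 1, 0, 1 and 1 with an estimated correlation, and with fry 0 in smxl5-1, 2 in smax1-2 and 5 for the double mutant against smxl5-1. With quantile normalization the photosynthesis median in smax1-2 was 1.78e-15 (adjusted p = 0.8).

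Leaving out 1 library gave 30 to 130, 203 to 323, 12 to 17, 453 to 1239 and 259 to 364 called genes and 3 to 10 lists in smxl5-1. It gave 5 to 9 genes shared by the double mutant and smax1-2, 14 to 41 by the double mutant and smxl5-1, and r of 0.3184 to 0.4868 for the first pair.

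Directions turned for 45 single values outside the fits with a library left out, with 4177 the same, 574 no longer called and 66 newly called, and the cause was not tested. With classes =, c and j the log2 fold change was 0.27 for KNOLLE in smxl5-1, 0.65 for PAD4 in the double mutant, and against smxl5-1 0.025 for ARR6, 0.26 for CKX5 and 0.87 for PAD4. With the plain sum it was 0.63 for SMXL4, 0.072 for MGD2, -1.29 for ICL and -0.76 for LRX1 in smxl5-1. In the double mutant it was -1.01 for UGT75C1, -0.74 for ICL, -0.014 for CIA2, -0.083 for PWD, 0.23 for AKINBETA1, 0.44 for SEN1, -0.62 for TPS5, 0.45 for PAD3 and 0.14 for HRS1. In smax1-2 it was -0.31 for SMXL5, 0.77 for LHCA2, 0.13 for SQD2 and 1.02 for YUC8. Against smxl5-1 it was -0.28 for SMXL4, -0.54 for SMAX1, -0.70 for MAX1, -0.23 for OPS, -0.29 for PGM1, -0.27 for SBE2.1, -0.33 for MEX1, 0.39 for CKX5, 1.32 for ARR5, -0.10 for ICS1 and 0.25 for G6PD3. Against smax1-2 it was -1.77 for SMXL4, 0.045 for SMXL6, 0.022 for DLK2, -0.16 for SEX4, 0.29 for AKINBETA1, 0.53 for SEN1, 0.59 for ASN1 and 0.11 for PAD4. With plain length it was 0.10 for LHCA2 in smax1-2, -0.00016 for SMAX1 and 0.27 for ARR5 against smxl5-1, and -0.39 for SMXL4 against smax1-2. With 1 library left out SMAX1 against smxl5-1 ran from -0.057 to 0.23.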

Other observations

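Of the tests in this part, the one on adjacent genes and the one on assembly that fails at random were set down before their results were seen. The tests on annotation terms, on the splits of the libraries, on genes listed in exactly 3 libraries, on the SMXL5 pieces, on genes around the mutated genes and on sugar, phosphate and assembly completeness were chosen only after the result was seen. The genes that the report does not name were chosen after their values were seen.

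Terms in the notes of the reference annotation were tested for called genes with 1-sided Fisher's exact tests of 242 terms over 7603 annotated genes, adjusted over the terms of a comparison and direction. Some terms, such as water deprivation and defence, are close to lists of the report. In smxl4-1 smxl5-1 against smxl5-1 the lower genes held 14 of 57 genes of defence against fungus (adjusted p = 1.74e-05), among them the chitinase gene CHI-B, the osmotin gene OSM34 and the chitin receptor gene CERK1. They also held 26 of 229 genes of the salt stress term (adjusted p = 0.000509), 11 of 59 of the wounding term (adjusted p = 0.00226), 11 of 60 of the stress term (adjusted p = 0.00226), 14 of 127 of the oxidative stress term (adjusted p = 0.0336) with peroxidase genes such as PER37, PER39 and PER69, and 5 of 19 of the gibberellin term (adjusted p = 0.0336) with the peptide genes GASA5, GASA7 and GASA14. The biotic stimulus term had 5 of 19 genes lower (adjusted p = 0.0336), and 4 of 19 against smax1-2 (adjusted p = 0.0157). The higher genes held 23 of 249 genes of proteolysis (adjusted p = 0.0106), such as SCPL9 and SCPL10, and against smax1-2 it was 16 of 249 (adjusted p = 0.00204). Against WT, the higher genes of smxl4-1 smxl5-1 held 7 of 70 genes of the water deprivation term (adjusted p = 0.0261), among them HIS1-3, ATHB-7 and LTP4.

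Some genes were listed in all 3 libraries of 1 genotype and in no other library. In smxl4-1 smxl5-1 these include GSTF5 (3.002, 3.16 and 1.96 FPKM), the peptide gene CLE6 (1.41, 1.53 and 1.84 FPKM), LBD1 (1.41, 1.36 and 4.56 FPKM) and AT3G25011 (3.53, 3.83 and 5.91 FPKM). In smxl5-1 they include AT2G34000 (3.65, 1.98 and 2.78 FPKM) beside NIT2 and AT4G01700, and in smax1-2 AT1G30250 (3.02, 2.71 and 5.38 FPKM) and AT1G50390 (2.07, 1.96 and 3.05 FPKM). AT5G57720, which lies next to SMAX1 on the other side from AT5G57700, was listed in smax1-2 alone (1.36, 0.794 and 1.02 FPKM) and was too low to be tested. In WT alone these were AT5G27500, MIR171B, AT3G01329 and AT3G47100. HEI10 and MRD1 overlap, so their pieces cannot be assigned to 1 of them with certainty, and both were at or near 0 in the 6 libraries labelled with smxl5-1.

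For each of the 5 comparisons 1 of the 10 splits of the 6 libraries, the real one, gave as many called genes, and 10 splits are too few for a share under 0.05. The real counts and the highest of the other splits were 145 and 4 in smxl5-1 against WT, 466 and 3 in smxl4-1 smxl5-1 against WT, 16 and 5 in smax1-2 against WT, 1315 and 83 in smxl4-1 smxl5-1 against smxl5-1, and 546 and 5 in smxl4-1 smxl5-1 against smax1-2.

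The first pattern is that called genes such as NIT2 and AT5G27500 were unlisted in every library of one group, which may come from the assembly or from expression. Assembly that succeeds in single libraries at random is argued against, since of 111 genes listed in exactly 3 libraries at 1 FPKM or more, 16 were listed in the 3 libraries of 1 group, where 2.02 would be by chance (exact binomial p = 2.27e-10, and p = 2.33e-17 with no minimum and 0.0018 at 5 FPKM). Assembly that fails at random stays open, as the limit decides it. Over a mean FPKM limit, 2 of 82 genes unlisted in exactly 3 libraries were so in 1 group (1.49 by chance, exact binomial p = 0.663). With no limit it was 19 of 343 (6.24 by chance, exact binomial p = 2.33e-05, and 0.0096 at 1 FPKM). Fragments assembled into a piece of an adjacent gene stay open too, since 40.3% of these genes (27 of 67) had an adjacent gene that moved the opposite way, against 16% of called genes listed in both groups (214 of 1335, Fisher's exact p = 6.01e-06), between the bounds of 20% and 50% set beforehand. A difference in expression between the genotypes was not tested apart from these.

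The second pattern is that SMXL5 was higher in the libraries labelled smxl5-1. A rise of most genes around SMXL5 by as much is argued against, since the highest log2 change of the 20 nearest tested was 1.61. A smaller rise stays open, as the fit called 38% of simulated changes of 0.5. ORP4C alone (5%) was called higher, and not without WT replicate 1 or 2 or smxl5-1 replicate 1 or 2 (0.0506 to 0.0636). A rise of single neighbours such as adjacent AT5G57123 (1.299, SE 0.311) is not excluded. A piece shared with another gene or a partial assembly stays open, since the exact-match pieces made up 0, 72 and 82.9% of the value in the 3 libraries, a median of 72%. Higher transcription around an insertion may raise genes beside the mutated genes, and 4 of 80 values of the nearest genes, over every genotype with the mutation, were called (1.16 by chance, 1-sided exact p = 0.0284, stratified by comparison). All 4 were higher, ORP4C in smxl5-1, AT5G57700 in smax1-2, and ABI2 (0.83, adjusted p = 0.0106) and CIA2 (0.46, adjusted p = 0.0133) beside SMXL5 in smxl4-1 smxl5-1. It stays open, since calls among these genes were seen before the test was chosen and 0 of the 20 genes beside SMXL5 were called in both genotypes that carry smxl5-1. AT5G57123 rose alike in both, by 1.299 and 1.29 (adjusted p = 0.0882 and 0.0645), but missed the threshold in each. Of the called ones, ORP4C (adjusted p = 0.011) and CIA2 (adjusted p = 0.00349) differed between these genotypes. ABI2 was not called without WT replicate 1 (adjusted p = 0.0532), nor CIA2 without smxl4-1 smxl5-1 replicate 3 (adjusted p = 0.0577), and with the plain sum of FPKM CIA2 stood at -0.014. The kind of lesion is not given in the labels, and a truncated or stabilised transcript was not tested.

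The third pattern is that anthocyanin and starch genes were higher in smxl4-1 smxl5-1 than in WT. Different assembly completeness of the libraries is argued against, since 100% of the called anthocyanin genes (13 of 13) were also called with the share of exact-match pieces as covariate. A sugar surplus stays open, since the value it needs, a median of -0.359 for sugar-starvation genes with 3 called lower (SEN1, AKINBETA1 and ASN1), was known before the test was chosen. With the plain sum of FPKM SEN1 stood at 0.44 and AKINBETA1 at 0.23, and the list was not called with an estimated correlation (adjusted p = 0.192). A phosphate shortage stays open, since its list had a median of 0.0831 with 12 genes higher and 6 lower (quartiles -0.14 to 0.24), and the bound set for it, a median under 0.2 with no gene called, was dropped after the outcome was seen because genes that go both ways decide nothing. The mutations themselves remain a biological explanation that the design cannot separate from these.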
